A study of Homo sapiens with 704 samples.

How the data were processed

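Primary human cardiac fibroblasts grown out of heart tissue were followed as single cells while being reprogrammed toward a cardiomyocyte-like state. Per the labels' protocols, cells were transduced with a retrovirus carrying human MEF2C, GATA4 and TBX5 (MGT) on 1 transcript and a second virus carrying miR-133. Control cells received DsRed or tdTomato virus with an empty vector. Live cells were sorted, captured on Fluidigm C1 microfluidic chips, and their cDNA was made with a SMARTer kit and sequenced after Nextera XT library preparation. No unique molecular identifiers are named in the labels.

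The deposited values are a normalised signal made by the authors: read counts per gene scaled with SCnorm, per the table names. FastQC, TopHat2, HTSeq 0.6.1p1 and genome build hg19 are listed, per the submitters' processing notes; the SCnorm settings are not given in the sources used here. SCnorm scales genes in groups by how their counts depend on depth, so the values are a scaled signal for most genes. In the first table, of genes with a mean of at least 1, 25.2 to 25.4% had whole-number values in every cell of a plate, among them GATA4, primary miR-133, NPPA, NEBL and ACTA2. Whole in every cell of the table were 21 of 34 sarcomere genes. The total of such genes varied between cells of a plate by 14.4 to 24.0% (coefficient of variation), against 1.81 to 3.96% for the others. Whether they were scaled is not given in the sources used here, so depth differences may remain in them. The first table holds 329 cells of plates D0HCF, D3M1, D3M2 and D3UN in 23715 lines. The second holds 337 cells of plates D3M3, D5M1, D7M1 and D9M1 and 14 D3UN cells in 23716 lines. They were deposited as separate tables; whether they were normalised together is not given in the sources used here, and ratios were formed only within a table. For the 14 D3UN cells found in both, second-table values lay at a single log2 ratio of -0.09 to first-table values, over 7723 genes with a mean of at least 10. Such a factor turns whole numbers into other values. Whole-number values therefore cannot mark unscaled genes in those 14 cells. The mixed plates have no first-table values, so the factor could not be checked for them. Depth differences may remain throughout the second table too.

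The original depth of each cell was not recovered. Among values under 20, a median of 13.6% per cell in the first table and 6.67% in the second were whole multiples of the cell's smallest value, with a tolerance of 0.01. No count test was therefore run. No gene was named in 28 lines of the first table, which held 0.228% of all values and were left out. The 105 lines of XIST and Y-linked genes were left out of each table. Lines for vector sequences (the DsRed, tdTomato, integrase-region, packaging-region, puromycin and primary miR-133 sequences) were described on their own and were not eligible as named genes. The gene identifiers are symbols, and no coordinates are given because the files hold none.

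Cells were assigned to plates by their labels. The labels name no separate cultures or donors for the cells of a plate, so each plate is 1 sample: no p-value, standard error or count of changed genes was formed from cells. The only plates with the same label are D3M1 and D3M2, and their gap is the only measure of spread between like plates. The rule written before the data were examined was never to divide cells of the mixed plates by their values. It was departed from in 1 alternative, which leaves out the D3M3 cells of cluster 4, and in means of HSPA1A and HSPA1B inside and outside that cluster. Each gene's ratio is log2 of plate means plus a pseudocount of 1, which understates differences of genes with low values. D3M1 and D3M2 were given equal weight.

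Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. A cell counted as having a gene when its value was above 0, and a threshold of 10 was the alternative. A value of 0 is a gene listed at 0 in the normalised table.

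Named genes were chosen by a rule written before the data were examined. Per comparison it took the 12 genes with the most positive and the 12 with the most negative ratio. Eligible genes had a mean of at least 20 and values in at least 30% of cells of the higher group. Where D3M1 and D3M2 were the higher group, each of them had to meet both minimums. The share of cells with a value had to lie on the same side, or be at least 95% in both groups. Where D3M1 and D3M2 entered, each had to differ by at least 1 on the log2 scale in the same direction. The rule also covers MEF2C, GATA4, TBX5 and examples from 16 gene lists, namely the members with the largest ratio on the side of the list's median. COL1A1, IFNB1, the median levels of single genes and the genes listed at 0 were partly singled out after their values were seen.

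The lists were fixed before the data were examined. They cover cardiac sarcomere, ion handling and natriuretic peptides, other cardiac transcription factors, fibroblast matrix, smooth muscle, cell cycle, interferon response, inflammatory cytokines, TGF-beta and BMP targets, cardiac energy metabolism, nuclear-encoded and mitochondrially encoded respiratory chain, unfolded protein response, p53 targets, immediate early genes and reported miR-133 targets. The mitochondrially encoded list had 0 measured members. For each list the median ratio over members with a mean of at least 1 on either side was given, with the number of members 2-fold higher or lower (in each of D3M1 and D3M2 where both entered). The median's percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these plates only.

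Cells of each table were clustered with the Leiden method on log2(value + 1), from the 2000 most variable genes present in at least 10 cells, 20 principal components, 15 neighbours and resolution 0.6. Clusters were described with marker genes fixed before the data were examined. No doublet caller was run. Per the labels' protocols, wells were chosen from images as holding single healthy cells.

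Alternatives were the mean of log values, pseudocounts of 0.1 and 10, no minimum or a minimum mean of 10, rescaling cells to the table's median total, leaving out the highest and lowest 5% of cells per gene, leaving out D3M1 or D3M2, and other clustering settings. Restricting D3UN to the 14 cells held in both tables, leaving out the D3M3 cells of cluster 4, and leaving out list members with whole values in every cell of the first table were added after the data were seen.

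The calculations were tested on simulated data, made by planting known folds in 200 of 13361 genes in 1 of the 2 random parts of nearly equal size into which D0HCF was divided. Planted 2-, 4- and 8-fold differences gave median log2 ratios of 1.03, 1.97 and 2.99. Of the 12 genes named as higher, 11 were planted. A list of 25 genes planted at 2-fold lay at the 100th percentile and an unplanted list at 30.9. With 200 genes planted at 8-fold, 100% of cells fell in a cluster mostly of their own part. Planted genes had a mean of at least 20 and both parts came from 1 plate. The simulation therefore does not cover genes with lower values or differences between plates. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.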

Results

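The data comprised 652 single-cell transcriptomes from 8 plates, out of 704 sequenced wells. D0HCF held 85 uninfected fibroblasts from day 0. D3M1 (91 cells) and D3M2 (85 cells) held cells 3 days after transduction with MGT and miR-133. D3UN held 68 cells from day 3, a mix of DsRed-transduced and uninfected cells at 3:1. D3M3 (86 cells, day 3), D5M1 (75, day 5), D7M1 (82, day 7) and D9M1 (80, day 9) each mixed MGT and miR-133 cells with tdTomato control cells at 3:1, and the labels do not say which cell is which. The median total of normalised values per cell lay between 960942 and 986318 in the first table and between 917343 and 923049 in the second. The median number of genes above 0 per cell ranged from 8963 in D3M3 to 9811 in D0HCF. With each plate counted as 1 sample, the values below have no replicate check apart from the gap between D3M1 and D3M2.

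The transgenes were examined first. MEF2C, a transcription factor of heart and muscle, had a mean normalised value of 20.6 in D0HCF, 252 in D3M1, 82.8 in D3M2 and 52.7 in D3UN. TBX5, a T-box factor of heart development, had means of 5.10, 60.7, 23.03 and 2.87 in the same order. GATA4 differed little, with means of 26.95, 34.5, 35.8 and 35.8. Primary miR-133 RNA was listed at 0 in D0HCF and D3UN and averaged 1042 in D3M1 and 98.3 in D3M2. DsRed had values in 63 of 68 D3UN cells (92.6%, interval 83.7 to 97.6) and in 0 of 91 D3M1 cells, which allows a share of up to 3.97%. Above 10, the DsRed share was 77.9% (interval 66.2 to 87.1), where the labels' mixing ratio gives 75%. MEF2C and TBX5 means were thus higher in the MGT plates and primary miR-133 RNA was found only there. The mean of GATA4, which lies on the same transcript, was not higher than in D3UN. Its medians per cell were 10 in D0HCF, 13 in D3M1, 7 in D3M2 and 5 in D3UN. The D3UN mean of GATA4 was 14.7 in the 14 cells that both tables hold and 41.2 in the other 54. Values of the factors may pool reads of the cell's own gene and of the transgene; whether reads of the transgene's GATA4 part are counted under GATA4 is not given in the sources used here. GATA4 and primary miR-133 had whole-number values in every first-table cell, so depth differences may remain in them. Retroviral packaging-region RNA was above 10 in all 68 D3UN cells, although the labels describe a share of uninfected cells in that plate. In the mixed plates D3M3, D5M1, D7M1 and D9M1, mean MEF2C was 210, 584, 247 and 496, against 17.7 in the 14 D3UN cells of that table. Mean TBX5 in those plates was 43.6, 103.4, 54.02 and 96.5, against 1.72 in the 14 D3UN cells. Mean GATA4 was 30.4, 24.8, 17.1 and 24.6, against 13.8 in the 14 D3UN cells.

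**Figure D1:**
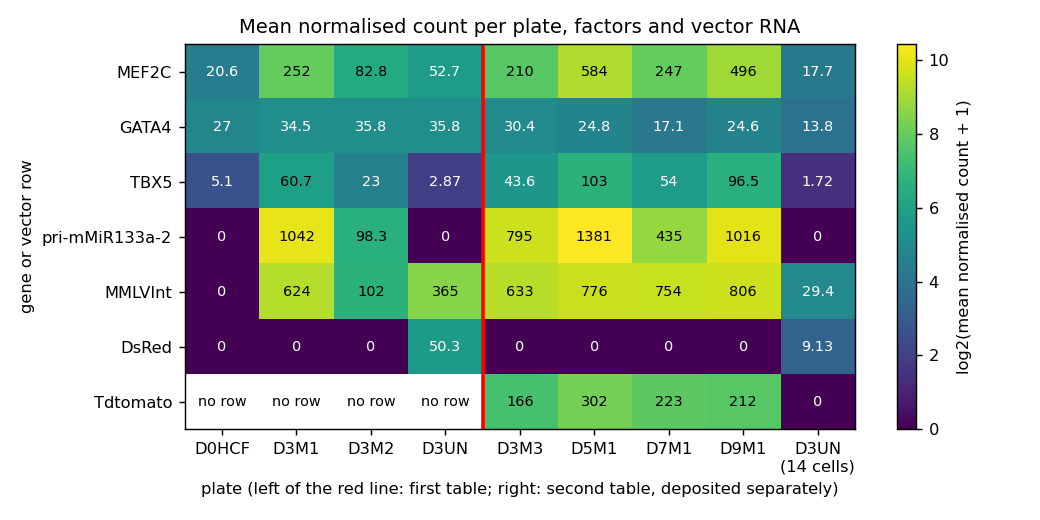
Mean normalised values of the transgenes and vector sequences by plate, with the tables shown separately because they were deposited separately. MEF2C and TBX5 means were higher in D3M1 (252 and 60.7) than in D3M2 (82.8 and 23.03), while GATA4 means were 34.5 and 35.8.

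The day-3 MGT and miR-133 plates were set against uninfected day-0 fibroblasts to ask which genes differed after 3 days. TNNT2, cardiac troponin T, was listed at 0 in all 85 D0HCF cells. It averaged 152.3 in D3M1 (above 0 in 80 of 91 cells, 87.9%, interval 79.4 to 93.8) and 11.8 in D3M2 (22 of 85 cells, 25.9%, interval 17.0 to 36.5). Above a value of 10, the TNNT2 shares were 50.5% in D3M1 and 15.3% in D3M2. NEBL, a Z-disc protein, was also listed at 0 in D0HCF and averaged 47.3 in D3M1 and 16.2 in D3M2. CRYAB, a small heat shock protein abundant in heart, averaged 335 and 54.2 against 13.7. The sarcomere list had a median log2 ratio of 2.45 over 25 measured members, at the 100th percentile of matched lists, and 8 members were at least 2-fold higher in each plate. Its median was 3.31 in D3M1 and 0.59 in D3M2, and on means of log values it was 0.53.

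Of 32 interferon response genes, 28 were at least 2-fold higher than at day 0 in both D3M plates and 0 were lower, with a median log2 ratio of 3.85. IFI44L averaged 1056 against 5.88, and MX1, an antiviral GTPase, 519 against 4.49. Of 30 cell cycle genes, 29 were at least 2-fold lower in both plates, with a median of -3.31 (-4.23 for D3M1 and -2.68 for D3M2). CDC20, an activator of the anaphase-promoting complex, averaged 1.22 in D3M1 and 11.01 in D3M2 against 152.2. PLK1, a mitotic kinase, averaged 3.21 and 4.87 against 94.1, and MKI67, a marker of proliferating cells, 1.55 and 30.6 against 283. Smooth muscle contractile genes had a median of 1.29, with 6 of 14 at least 2-fold higher, and ACTA2, smooth muscle actin, averaged 2579 against 178.1. The p53 target list had a median of 0.80 (CDKN1A 234 against 70.8) and the immediate early list 0.96 (FOS 267 against 55.9). Other named genes outside these lists included SORBS2 (284 in D3M1 and 56.9 in D3M2 against 1.47) and RNASE1 (323 and 83.99 against 3.09). The fibroblast and matrix list differed less, with a median of 0.32, 2 of 29 members higher and 1 lower. LUM, a collagen-binding proteoglycan, averaged 789 against 170.7. The cardiac ion handling (-0.02) and other cardiac transcription factor (-0.03) lists had medians near 0.

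The comparison with D3UN, a plate of the same day that carried DsRed virus, asks what differed beyond time in culture and transduction. Among the genes eligible for the ranking, TBX5 had the largest positive ratio (60.7 in D3M1 and 23.03 in D3M2 against 2.87). It was followed by RNASE1 (323 and 83.99 against 24.6), CD14, a co-receptor for lipopolysaccharide (140.7 and 35.9 against 11.4), TGFB3 (108.8 and 22.7 against 9.79) and NREP (478 and 210.5 against 57.3). TNNT2 averaged 152.3 and 11.8 against 1.33, but was not eligible for that ranking because its D3M2 mean was under 20. The sarcomere list had a median of 1.81 at the 100th percentile, with 4 of 24 members at least 2-fold higher in both plates; it was 2.38 in D3M1 and 0.33 in D3M2. CXCL10, an interferon-induced chemokine, averaged 2.67 and 26.8 against 1449, BIRC3, an NF-kB-induced apoptosis inhibitor, 1.03 and 1.18 against 181.6, and OASL 20.4 and 6.69 against 549. IFNB1, interferon beta, was listed at 0 in D3M1, had a value in 1 of 85 D3M2 cells, and averaged 316 in D3UN. That D3UN mean came from a minority of cells: the median was 2.35, and 20.6% of cells were above 10. CXCL10 and BIRC3 were uneven as well. The D3UN median of CXCL10 was 86.3, with 73.5% of cells above 10, and in D3M2 2 of 85 cells were above 10. BIRC3 averaged 442 in cluster 5 of the first table (27 cells, all D3UN), which it helps to lead, and 2.41 in all other cells.

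Against D3UN, 16 of 32 interferon response genes were at least 2-fold lower in both D3M plates (list median -1.27), and so were 18 of 24 inflammatory genes (median -2.27), with CXCL1 at 29.2 and 104.1 against 1004. The unfolded protein and integrated stress response list had a median of -1.0, with 5 of 15 members lower, and DDIT3, a transcription factor of that response, averaged 50.5 against 430. The interferon and inflammatory directions depended on which D3UN cells were used. With the 14 D3UN cells that both tables hold, their medians were 1.22 and 0.48, the opposite sign in each case; the stress response median was -0.56, and the matrix median went from 0.34 to -0.49. Cell cycle genes had a median of 0.66, but -0.05 for D3M1 alone and 1.15 for D3M2 alone.

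D3UN was compared with D0HCF to describe day 3 without the cardiac factors. All 32 interferon response genes were at least 2-fold higher in D3UN, with a median log2 ratio of 5.67. RSAD2 averaged 1678 against 3.11 and MX1 1319 against 4.49, while CXCL10 and IFNB1 were listed at 0 in all 85 D0HCF cells. Of 24 inflammatory genes 21 were higher (median 2.52), including IL1A (196 against 10.5), and VCAM1, an adhesion molecule, averaged 147.2 and was listed at 0 in D0HCF. All 30 cell cycle genes were at least 2-fold lower (median -3.84), with MKI67 at 3.63 against 283. The stress response list (median 1.22, 9 of 15 higher) and the p53 target list (median 1.28, 10 of 14 higher) were higher too, with DDIT3 at 430 against 36.7 and PMAIP1, a pro-apoptotic protein, at 187 against 10.5. Smooth muscle genes had a median of 0.79 (ACTA2 1804 against 178.1). The sarcomere list had a median of 0.95, with 8 of 16 members higher, led by ACTN2, sarcomeric alpha-actinin (64.1 against 0.56). The matrix list had a median of 0.16, which was -0.30 on means of log values. Reported miR-133 targets had a median of -0.44 in this plate, where primary miR-133 RNA was listed at 0, against -0.26 for D3M1 and D3M2.

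In the like-labelled plates D3M1 and D3M2, NPPA, atrial natriuretic peptide, averaged 108.6 in D3M1 and 0.48 in D3M2, and TNNT2 152.3 and 11.8. MYH11, smooth muscle myosin, averaged 56.6 and 4.02. CDK1, the mitotic cyclin-dependent kinase, averaged 2.14 and 71.1, and TOP2A 2.47 and 62.1. Of 25 sarcomere genes 18 were at least 2-fold higher in D3M1 (median 1.60, and 2.35 without members of whole values), and of 30 cell cycle genes 19 were at least 2-fold lower (median -1.30). The ion handling and natriuretic list had a median of 0.06 (4 of 16 higher, 2 lower) and other cardiac transcription factors 0.22 (2 of 11 higher, 1 lower). Over 13157 genes with a mean of at least 1, 1310 (9.96%) were at least 2-fold apart, and 3.25% of 1909 genes with a mean of at least 100. The median cell had values for 14 of 34 sarcomere genes in D3M1 and 9 in D3M2, against 8 in D0HCF and 9 in D3UN.

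In the second table, the day-3 mixed plate D3M3 was compared with the 14 D3UN cells of that table. COL1A1, the type I collagen alpha chain, averaged 1262 against 6961, PDGFRB 2.25 against 39.5, CNN1, calponin, 0.84 against 56.6, and MFAP4 3.53 against 383. SOD2, mitochondrial superoxide dismutase, averaged 321 against 5.85, and ISG15 1296 against 168.7. The matrix list had a median of -1.06 (15 of 30 lower), the smooth muscle list -1.35 (9 of 15 lower), the interferon list 1.61 (22 of 31 higher) and the inflammatory list 1.20 (12 of 21 higher). The cell cycle median was 1.71 (19 of 30 higher), and 0.23 without the highest and lowest 5% of cells. The sarcomere median of 0.69 became -0.38 without those cells. CXCL10 went the other way from its list, with 0.08 against 42.5. Those 14 cells had lower interferon, inflammatory and cell cycle genes than the other 54 D3UN cells of the first table (list medians -3.25, -3.22 and -1.16). The same 14 cells had higher matrix and smooth muscle genes than the other 54 (1.30 and 1.34), similar in size to the D3M3 medians of these lists. They also had less integrase-region RNA (31.4 against 452) and DsRed (9.75 against 60.9), and the labels do not say whether they were DsRed-transduced or uninfected. What D3M3 is compared with here is therefore not known.

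The mixed plates of day 5, 7 and 9 were each compared with D3M3 to follow reprogramming over time. Mean NPPA was 10.8 at day 3, 1525 at day 5, 1131 at day 7 and 12214 at day 9, and the share of cells above 10 was 10.5% (interval 4.90 to 18.9), 36% (25.2 to 47.9), 50% (38.7 to 61.3) and 87.5% (78.2 to 93.8). The day-9 share lies above the 75% of MGT cells that the mixing ratio gives, so it is not read as a share of reprogrammed cells. Mean TNNT2 was 28.2, 203, 150 and 727, with 16.3%, 30.7%, 37.8% and 48.8% of cells above 10. Between the like-labelled day-3 plates D3M1 and D3M2 the log2 ratio of TNNT2 was 3.58. Their means were 152.3 and 11.8, with 50.5% and 15.3% of cells above 10, so the day-5 and day-7 values are read with that gap in mind. The log2 ratios of NPPA against D3M3, 7.01, 6.58 and 10.01, compare with 6.21 between the like-labelled D3M1 and D3M2; differences between the later days were not tested. At day 9, ACTC1, cardiac alpha-actin, averaged 102.1 against 0.04, and SLN, sarcolipin of the atrial calcium pump, 436 against 1.56. TNNC1 averaged 89.8 against 1.36 and MYL7, atrial myosin light chain, 133.1 against 3.76. Named genes outside the cardiac lists included APOD (565 against 5.68), UCP2 (215 against 4.99) and IL18 (140.97 against 3.24).

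The median ratio of all genes with a mean of at least 1 was itself 0.35, 0.14 and 0.24 at day 5, 7 and 9, and list medians are read against it. Sarcomere medians were 2.29, 1.69 and 3.47, with 13 of 23, 16 of 25 and 22 of 26 members at least 2-fold higher; on means of log values the day-5 and day-9 medians were 0.68 and 1.37. The median between D3M1 and D3M2 was 1.60, close to the day-7 value. Without the D3M3 cells of cluster 4, an alternative described below, the medians were 1.51, 0.90 and 2.95. The ion handling and natriuretic list had medians of 0.85, 0.91 and 1.11. MYH6 and MYH7, the cardiac myosin heavy chains, were listed at 0 in all cells of these plates. The median cell had values for 9, 11, 11 and 14 of 34 sarcomere genes from day 3 to day 9.

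**Figure D2:**
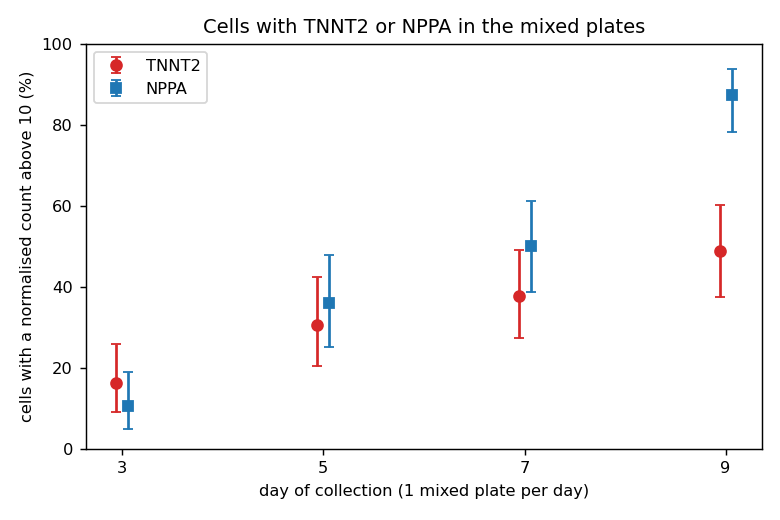
Percent of cells with NPPA or TNNT2 values above 10 in the mixed plates D3M3, D5M1, D7M1 and D9M1, with exact 95% intervals for counting error. Above 10, NPPA was found in 10.5% of D3M3 and 87.5% of D9M1 cells, where the mixing ratio gives 75% MGT cells, and TNNT2 in 16.3% and 48.8%.

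The interferon list median against D3M3 was -0.67 at day 5 (11 of 31 at least 2-fold lower), -2.73 at day 7 (28 of 30) and -2.69 at day 9 (27 of 30), and on means of log values the day-5 median was -1.71. IFIT1, an interferon-induced RNA-binding protein, averaged 982 at day 3, 82.8 at day 7 and 45.8 at day 9, and ISG15 1296, 100.3 and 126.8. The unfolded protein response list had medians of -0.59, -0.90 and -0.56, with 5, 7 and 5 of 15 members at least 2-fold lower. HSPA5, the main chaperone of the endoplasmic reticulum, averaged 1273 at day 3 and 368, 326 and 506 later, but its medians per cell were 531, 219, 238 and 462. Without the 37 D3M3 cells of cluster 4 the list medians were 0.39, -0.06 and 0.15, and the interferon medians -0.85, -2.65 and -2.68. That alternative was chosen after the data were seen and departs from the rule against dividing mixed plates. The cluster is made partly from stress genes, so these values show only how far the medians depend on those cells. TGF-beta and BMP targets had medians of 0.60, 0.46 and 0.39, with BAMBI at 26.7 at day 3 and 230, 60.3 and 164.9 later. Inflammatory genes had medians of 1.04 and 0.78 at day 5 and 7 and of 0.00 at day 9, with LIF at 4.48, 34.6 and 30.98 on days 3, 5 and 7. The matrix list had medians of 0.10, 0.04 and -0.08, which on means of log values were -0.51, -0.24 and -0.84.

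**Figure D3:**
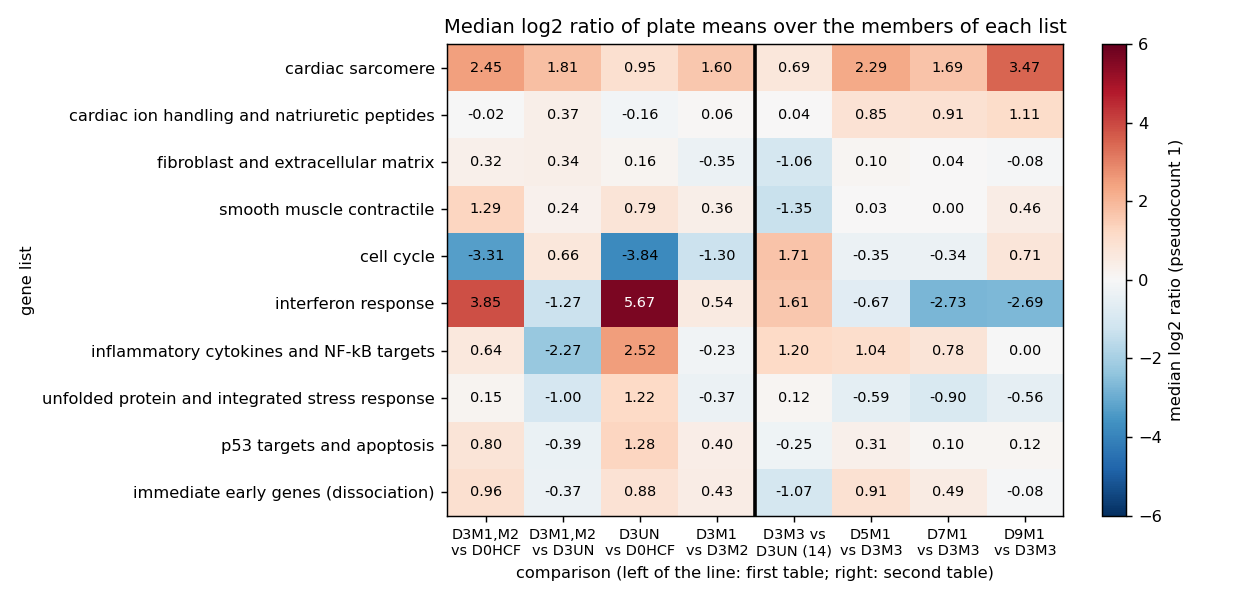
Median log2 ratio of 10 of the 16 gene lists (lines) in each comparison (columns), with the value printed in each cell and the color scale in log2 units. The sarcomere medians of D5M1, D7M1 and D9M1 against D3M3 were 2.29, 1.69 and 3.47, and the interferon medians were -0.67, -2.73 and -2.69.

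Clustering gave 5 groups of cells in the first table and 7 in the second. Cluster 3 of the first table was cardiomyocyte-like, with 7 of 14 fixed cardiomyocyte markers detected, among them TNNT2, TNNC1, ACTN2 and MYL7. Cluster 2 of the second table was also cardiomyocyte-like, with 8 of 14 markers detected, including ACTC1 and TNNI3. In each of these clusters 8 of 10 fibroblast markers, such as COL1A1, DCN and PDGFRA, were detected as well. Their level differed: against the other cells of its table, the median log2 ratio of the 10 fibroblast markers was -0.13 in the first-table cluster and -1.75 in the second-table cluster. The sizes of these 2 cardiomyocyte-like clusters are not compared between plates, because the genes that lead them are the genes compared above. Some clusters came from 1 plate, such as cluster 5 of the first table (27 cells, all D3UN) and cluster 4 of the second (37 cells, all D3M3), and such a cluster can reflect the plate.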

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

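Every test of an explanation in this part was chosen after the result it measures had been seen, apart from the test for a few extreme D3UN cells, which was set beforehand. The condition that picked out the cell cycle and tdTomato values was also chosen after values had been seen.

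The cell cycle list of the mixed plates stood on opposite sides of D3M3 at different days, with medians of -0.35 at day 5, -0.34 at day 7 and 0.71 at day 9; without the D3M3 cells of cluster 4 they were -0.64, -0.63 and 0.37. They are smaller in size than the -1.30 between D3M1 and D3M2, and the difference between days was not tested. CDK1 averaged 27.7 at day 3 and 0.59 at day 5, while BIRC5 averaged 27.9 at day 3 and 185.5 at day 9. Few cells carried much of these values. In cluster 7 of the second table, which cell cycle genes lead, BIRC5 averaged 1121, against 7.16 elsewhere. That cluster held 3 of 86 D3M3, 1 of 75 D5M1, 2 of 82 D7M1 and 10 of 80 D9M1 cells. tdTomato RNA entered no comparison and had values in 76% of D5M1, 45.1% of D7M1 and 53.8% of D9M1 cells, against 0 of 14 D3UN cells, which allows up to 23.2%. In D3M3 the share was 17.4% (interval 10.1 to 27.1). Above a value of 10 the later shares were 36% (25.2 to 47.9), 31.7% (21.9 to 42.9) and 27.5% (18.1 to 38.6), where the labels' mixing ratio gives 25%.

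Cardiac sarcomere genes were higher in D3M1 than in D3M2, although the plates share a label. A lower yield of genes in D3M2 is argued against by its median of genes per cell, which was 1.02 times that of D3M1. Whether some D3M2 cells lacked the miR-133 vector cannot be decided. Primary miR-133 RNA was above 10 in 85.9% of D3M2 cells (interval 76.6 to 92.5), with a median of 61 against 714 in D3M1. But RNA carried over between wells was not bounded. All 68 D3UN cells had packaging-region RNA above 10 despite a labelled share of uninfected cells. A lower amount of vector RNA per D3M2 cell remains open. It goes with a median log2 ratio of 1.60, D3M1 over D3M2, for 4 vector sequences, MEF2C, TBX5 and GATA4 (range -0.05 to 3.39). GATA4 was the lowest, with means of 34.5 in D3M1, 35.8 in D3M2 and also 35.8 in D3UN. By its means it may thus not follow the vector. Its medians per cell were 13, 7 and 5 in the same order, so GATA4 cannot decide on either side. A difference in culture between the plates was not tested, and no biological explanation was tested because the labels give these plates the same treatment.

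Interferon genes were lower in the MGT and miR-133 plates than in D3UN. Less vector RNA remains open: in D3M1, where the list median was -1.03, the integrase, packaging and puromycin sequences were at 1.71, 1.24 and 0.138 times their D3UN means (median 1.24), and in D3M2 at 0.279, 0.200 and 0.0625 times. A few extreme D3UN cells as the whole source are argued against by the median of -1.27 that was left without the highest and lowest 5% of cells. That the factor vector itself lowers these genes cannot be told apart from a property of the control plate, since only 1 plate of DsRed-transduced cells was analysed, and against its 14 cells held in both tables the list median was 1.22.

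The 14 D3UN cells held in both tables had lower interferon genes than the other 54. A smaller amount of vector RNA in them is consistent with integrase-region RNA at 0.0695 times that of the others (31.4 against 452); fewer genes detected is argued against by a ratio of 0.945 in median genes per cell. That they are the uninfected cells of the plate remains open: they are 14 of 68 cells (20.6%, interval 11.7 to 32.1, where the labels give 25%), with packaging-region RNA at 0.0793 times the mean of the others. Against it, 100% had that RNA above 10, 11 of 14 had DsRed above 0 (78.6%, interval 49.2 to 95.3) and 5 above 10, and 13 had puromycin RNA, but RNA carried over between wells was not bounded. If they are uninfected, the medians of 1.22 and 0.48 against these cells, interferon and inflammatory, compare transduced with uninfected cells.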

How the results depend on the processing

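Restricting D3UN to the 14 cells held in both tables, leaving out the D3M3 cells of cluster 4, and leaving out list members with whole values in every cell of the first table were chosen after the data were seen; all other alternatives were set before. Which lists are given in full here (sarcomere, matrix, interferon and cell cycle) was also settled after their values had been seen. No paired analysis was possible because no number in the labels links plates or cells across groups, and no comparison comes from a test. Changes were set against a limit per list or gene, the size of the D3M1 to D3M2 difference divided by the square root of 2. It is wide where these plates differ. For the sarcomere list it was 1.31, so the change from 0.69 to -0.38 in D3M3 against D3UN counted as less. The counts that follow therefore do not measure stability. Over all lists, 821 of 1020 alternative medians moved by less than the limit. The rest moved by more, 2 of them to the opposite sign from a median of at least 1 in size. Another 70 alternative medians changed sign from a value under 1 in size, and only some of these are given. Of 1152 alternative ratios of named genes, 763 moved by less than the limit, 384 by more and 5 to the opposite sign. At a threshold of 10, 58 of 95 shares of cells left their interval. The number of clusters stayed between 4 and 7 in the first table and between 7 and 9 in the second. Rescaling each cell to the table's median total moved 1 of 120 list medians. The totals were already nearly equal after normalisation, so this alternative could change little and is no check on depth. Depth before normalisation is unknown, so it sets no stated limit, and absence at 0 is a property of the deposited table. The cause was not tested for the values that follow.

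With the 14 D3UN cells, D3M against D3UN had the opposite sign for the interferon (1.22) and inflammatory (0.48) medians and for TMTC4 (-0.088), CXCL11 (0.96) and HERC5 (0.70); the matrix median was -0.49 and the cell cycle median 1.85. Without D3M1 or D3M2, against day 0 the sarcomere median ran from 0.85 to 3.11 and the interferon median from 3.24 to 4.03. Against D3UN they ran from 0.46 to 2.26 and from -1.76 to -1.03. These medians use the members measured with the remaining plate, so they differ from the per-plate medians over a common set of members (0.59 for D3M2 and 3.31 for D3M1 against day 0). The cell cycle median against D3UN was -0.05 without D3M2. Without members of whole values, the sarcomere median was 2.57 for D3M against day 0, 2.001 for D3M against D3UN, 0.68 for D3UN against day 0 and 2.35 for D3M1 against D3M2. In the same order cell cycle was -3.23, 0.83, -3.84 and -1.21, and the interferon list holds no such member. Leaving out the D3M3 cells of cluster 4 departs from the rule against dividing mixed plates by their values, and the cluster is made partly from stress genes. Without them DNAJB9 (0.55) and MANF (0.072) had the opposite sign at day 5, and the unfolded protein response medians of day 5, 7 and 9 were 0.39, -0.06 and 0.15. In the same order the sarcomere medians were 1.51, 0.90 and 2.95, matrix -0.03, 0.07 and 0.08, cell cycle -0.64, -0.63 and 0.37, and interferon -0.85, -2.65 and -2.68. The smooth muscle medians were -0.19, -0.10 and 0.28; the day-5 respiratory chain median was -0.06 and the day-7 p53 median -0.02.

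On means of log2 values, D3M against day 0 gave 0.53 for sarcomere and -4.45 for cell cycle, and D3M against D3UN gave 0.76 for matrix. D3UN against day 0 gave -0.30 for matrix, -4.78 for cell cycle and 6.11 for interferon. D3M3 against D3UN gave 0.46 for cell cycle and 2.30 for interferon. Against D3M3, day 5 gave 0.68 for sarcomere, -0.51 for matrix and -1.71 for interferon. Day 7 gave -0.24 for matrix and -3.71 for interferon. Day 9 gave 1.37 for sarcomere, -0.84 for matrix and -3.91 for interferon. A pseudocount of 0.1 gave 3.93 for sarcomere and 4.58 for interferon in D3M against day 0. A pseudocount of 10 gave 0.70 and 2.58 there, 0.47 for sarcomere in D3M against D3UN, 4.64 for interferon in D3UN against day 0 and 0.49 for cell cycle in D3M3 against D3UN. It gave -2.34 for interferon at day 7, and 1.70 for sarcomere and -2.17 for interferon at day 9.

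Without the highest and lowest 5% of cells, D3M against day 0 gave -4.29 for cell cycle and 4.33 for interferon, and D3UN against day 0 gave -5.24 and 6.37. D3M3 against D3UN gave -1.37 for matrix, 0.23 for cell cycle and a sarcomere median of -0.38 where all cells gave 0.69. The interferon medians of day 7 and 9 were -3.31 and -3.39. With no minimum mean, the day-5 sarcomere median was 0.90.

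At a threshold of 10, the share of cells with MEF2C was 34.1% in D0HCF, 85.9% in D3M2, 41.2% in D3UN, 88.4% in D3M3, 89.3% in D5M1, 80.5% in D7M1 and 80% in D9M1. With GATA4 it was 52.9% in D0HCF, 56% in D3M1, 43.5% in D3M2, 42.6% in D3UN, 47.7% in D3M3, 60% in D5M1, 45.1% in D7M1, 47.5% in D9M1 and 21.4% in the 14 D3UN cells. With TBX5 it was 11.8% in D0HCF, 86.8% in D3M1, 47.1% in D3M2, 59.3% in D3M3, 56% in D5M1, 53.7% in D7M1 and 51.2% in D9M1.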

Other observations

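No explanation is offered or tested in this part, and the items were picked after their values had been seen. The level of COL1A1 was spread more unevenly over cells in the later mixed plates. Its mean was 1262 in D3M3, 928 in D5M1, 870 in D7M1 and 1318 in D9M1, while the median cell had 935, 66.1, 183.5 and 252. NPPA was uneven as well: at day 9 its mean was 12214 and its median 80.8, although all 80 cells had a value above 0. In D3M1, TNNT2 averaged 152.3 with a median of 11.

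Medians of the energy metabolism list were small. FABP3, the heart fatty acid-binding protein, averaged 49.6 in D3M1 and 7.44 in D3M2 against 1.28 in D0HCF, and 57.3 at day 9 against 28.2 in D3M3. The energy list medians were 0.21 against D0HCF and 0.44 against D3UN, and 0.17, 0.27 and 0.28 at day 5, 7 and 9. The median against D3UN lay at the 99.75th percentile of matched lists, with 0 of 14 members at least 2-fold higher in each plate. The others lay between percentiles 20.9 and 82.4. Nuclear-encoded respiratory chain genes had medians between -0.11 and 0.15 in all 8 comparisons made. Heat shock genes HSPA1A and HSPA1B averaged 85.4 and 61.7 in D3M3 and 9.22 and 6.17 at day 9. In the 37 D3M3 cells of cluster 4 of the second table they averaged 184.7 and 132.9. The other 49 D3M3 cells had means of 10.4 and 7.97. Both genes are among those that lead the cluster, so this shows only how far the D3M3 means depend on those cells. The medians per cell of HSPA1A and HSPA1B were 21.7 and 11.02 in D3M3 and 1.07 and 0.702 at day 9. The reported miR-133 target UCP2 averaged 4.99 in D3M3 and 49.05, 33 and 215 at day 5, 7 and 9.

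Among the 68 D3UN cells, 13 of the 14 that both tables hold fell in cluster 1 of the first table, which contained 14 D3UN cells. COL1A1 averaged 7429 in those 14 and 1885 in the other 54, POSTN 3071 and 626, and DsRed 9.75 and 60.9. In the first table, 25.2 to 25.4% of genes with a mean of at least 1 had whole-number values in every cell of a plate (tolerance 1e-06). This share was 0 to 1.17% in the second. Whether the shares reflect a difference in scaling between the tables is not known. For the 14 shared D3UN cells, second-table values were first-table values times a single factor (log2 -0.09), which removes whole numbers. The mixed plates have no first-table values, so such a factor could not be checked there, and 0.439 to 1.17% of their genes were whole.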
